A study of Glycyrrhiza uralensis with 48 samples.

How the data were processed

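RNA was measured in 48 libraries of Glycyrrhiza uralensis (licorice) seedlings. Per the labels' protocols, 75 seeds were sown in each pot of 1900 g sterilised sand from desert regions, and seedlings were taken at 45 days. Aerial and underground parts were collected separately under 4 conditions, each with or without 2 mM silicon given as potassium silicate. The conditions were a distilled-water control, drought at 35 to 45% of saturation moisture, salt at 75 mM NaCl, and salt and drought together (salt-drought). The 2 plant parts, 4 conditions and 2 silicate levels make 16 groups with 3 libraries each. The replicate numbers come from the sample titles. Nothing in the labels says whether replicates came from separate pots, so p-values measure the spread between these libraries, and part of that spread is technical.

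Per the labels' protocols, 2 kinds of library were described. Full-length cDNA was amplified with 14 PCR cycles for nanopore sequencing on a PromethION, and RNA libraries were also prepared by an Illumina protocol. Which of them gave the expression values is not stated in the labels. The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by library depth) per gene and library, made with TopHat2 and Cufflinks per the submitters' processing notes. Versions, settings, strand handling and the genome build were not given in the sources used here. The table holds 38463 rows, of which 34445 carry the gene identifiers of the deposited annotation and 4018 are labelled as new genes, with no coordinates. The deposited annotation, a gene model file with start and end coordinates, lists 34445 genes and 36475 transcripts on 4853 scaffolds. Positions below are 1-based coordinates of that annotation, and its assembly name was not given in the sources used here. Neither file pairs an identifier with a gene name or description. Genes are therefore given by identifier, at most 2 that rose and 2 that fell per comparison, and the 35 gene lists fixed before the data were examined were not tested. In the annotation, 9485 genes overlap another gene. Without strand information, reads of such genes cannot be told apart, and the text says where a named gene is one of them.

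FPKM values are not counts, so no count model was used. Depth was estimated from the steps between low values of genes with at least 1500 nt of exon, and it came to 14.9 to 33.3 M fragments per library, with a median of 19.5 M. Only 36.5 to 48.6% of the low values then fell within 0.1 of a whole number of fragments, so fragment counts were not recovered. A step fixed in advance would give 20% by chance. Each step was instead chosen for the best match to the same values, so the depths are rough estimates. At these depths 1 FPKM at 1500 nt corresponds to 22.4 to 50.0 fragments. Fragments of amplified libraries without molecular identifiers are not independent molecules. An exact 0 can be a failed estimate in this table. In 173 cases over 89 genes a library was at 0 while both other libraries of its group held at least 10 FPKM, 32 of them in one library. Genes named below that are at 0 in a library are described as listed at 0.

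Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, with group means as the only terms and moderated variances (trend and robust options). A log2 change on this scale understates the change of genes at low FPKM. All 24 libraries of a plant part entered one fit, and all 48 entered the fits that compared the parts. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 23389 aerial, 24478 underground and, for both parts, 26335 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Where no gene was called, the number at an unadjusted p under 0.05 is given. Without any effect a share of 0.05 of the tested genes is expected there. In all, 15 pairwise comparisons and 11 interactions were made. The comparisons, tests, most alternative settings and the rule for genes to name were fixed before the data were examined. For a pair of groups these were the called genes with the largest rise or fall whose 3 values in one group lay beyond the 3 of the other and whose mean was at least 5 FPKM in one group. For an interaction the 3 genes with the smallest adjusted p under the same minimum were taken, with at most 2 in each direction. On simulated data for aerial drought against control, the test recovered 76% of 100 genes changed by 1 log2 unit and 95% of 100 changed by 2, and called 7 of 23189 unchanged genes. For underground drought against control it recovered 82% and 94%, and called 5 of 24278. The simulated noise was independent between genes and of equal spread in all groups, and only genes above about 5 FPKM were changed. Real libraries deviate together across genes and differ in spread, so these rates need not hold for them.

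Gene classes by plant part were defined after the data were seen, from the control libraries with silicate, which enter no comparison of a stress with its control. Genes at least 3 log2 units higher in one part, with no overlap between libraries, were called underground-enriched (799 genes) or aerial-enriched (807 genes). Genes higher underground by at least 1 log2 unit formed a wider class. By these rules the genes are lower in the other part, where those near 0 FPKM can hardly fall. Rises are thus favoured over falls there. Class shifts were tested with camera at a preset correlation of 0.01, adjusted over 42 class tests, and again with an estimated correlation, under which no class passed an adjusted p of 0.05. To look for RNA of the other part, 28 underground and 23 aerial marker genes were taken with at least 50 FPKM in one part and at least 200 times less in the other. The level of each marker in a library was expressed as a percentage of the mean of the matching group of the other part.

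Noise-corrected slopes of one response on another were computed across genes by removing the variance expected from the spread between replicates, with a jackknife standard error over libraries. These are descriptions across genes, which are not independent replicates. Within a plant part, libraries with the same replicate number did not deviate together (median r = -0.003 in aerial and -0.009 in underground parts). Between the parts, the control libraries with the same number did, with r from 0.24 to 0.32 across genes for the 3 pairs. The number was used as a block in alternative fits. The other alternatives were a pseudocount of 0.1 FPKM, no filter on low values, libraries rescaled to a common median ratio, a fit of the 2 groups compared alone, and each library left out in turn. After the data were seen, fits without the aerial libraries that held the most underground RNA, fits over genes not higher underground and a block shared by the parts were added, and overlaps between the parts were repeated against silicate-treated groups of the other part. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the annotation and the plots.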

Results

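Licorice seedlings grown for 45 days in sand under drought, salt or both were compared with unstressed seedlings, with and without silicate, in aerial and underground parts. Values are mean FPKM ± SD over 3 libraries, changes are on the log2(FPKM + 1) scale with their standard error (SE), and adjusted p-values are from limma. Libraries of a group correlated with a mean r of 0.961 in aerial parts (lowest 0.941) and 0.957 in underground parts (lowest 0.922). Between groups of a part the means were 0.941 and 0.938. The underground salt group held together poorly: its libraries correlated with one another at a mean of 0.928, 0.927 and 0.934 and with other underground groups at 0.928, 0.936 and 0.942. Aerial salt library 3 (0.951 and 0.952) and library 3 of underground salt with silicate (0.942 and 0.943) were also no closer to their own group. The highest r of any pair was 0.973, so no library is a copy of another. In all, 12481 genes changed in at least 1 of the 14 comparisons within a part.

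Underground and aerial parts differed most. In unstressed seedlings without silicate, 15457 of 26335 genes differed between the parts, 8202 higher and 7255 lower underground. With libraries of the same number paired it was 15664. The largest differences were in Glyur001944s00035546 (27310 ± 4780 against 3.76 ± 3.02, log2 change 12.66, SE 1.16, adjusted p = 1.51e-11) and Glyur001944s00035555 (19404 ± 6777 against 2.24 ± 1.31, 12.58, SE 1.15, adjusted p = 1.47e-11). Both lie on Scaffold01944, at 113 to 943 and 38750 to 39574 on the minus strand, and both overlap another annotated gene. The 11 genes of this scaffold, mapped with their levels in the figure, together made up 8.45 ± 1.74% of the summed FPKM in underground controls and 0.00188 ± 0.000754% in aerial controls. In the aerial direction, Glyur000822s00038922 (Scaffold00822, 48760 to 50881, overlapping another gene) reached 1337 ± 309 against 1.77 ± 2.16 underground (-9.16, SE 0.77, adjusted p = 1.76e-12). Glyur000318s00026566 (Scaffold00318, 46102 to 46883) reached 894 ± 196 against 1.54 ± 2.52 (-8.88, SE 1.03, adjusted p = 3.17e-09).

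**Figure D1:**
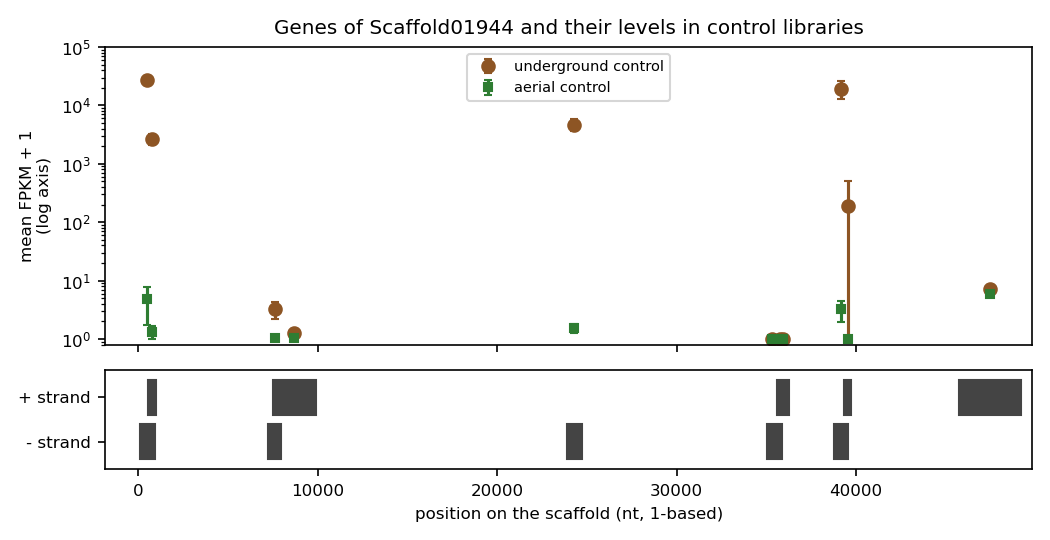
Genes of Scaffold01944 and their levels in the control libraries. Top, mean FPKM + 1 with SD over 3 libraries on a log axis; bottom, gene positions by strand.

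Drought alone changed 778 of 23389 genes in aerial parts, 389 in each direction. After rescaling of the libraries to a common median ratio, 782 genes changed, 285 higher and 497 lower, so the even split depends on the scaling. With only the drought and control libraries in the fit 54 genes changed, 15 higher and 39 lower, and of the 4 genes named here only Glyur000529s00019343 kept its call. The count fell to 514, 317 and 454 without control library 1, 2 or 3, and to 402 and 445 without drought library 1 or 2. Glyur000529s00019343 (Scaffold00529, 58811 to 59434, a single exon) fell from 269.5 ± 68.4 to 25.5 ± 5.65 (-3.34, SE 0.42, adjusted p = 0.000234). Glyur000080s00008691 (Scaffold00080, 224929 to 226329) fell from 379.6 ± 158 to 44.0 ± 13.0 (-3.02, SE 0.56, adjusted p = 0.00555). Glyur000078s00005378 (Scaffold00078, 88881 to 90386) rose from 3.46 ± 2.75 to 34.4, 55.3 and 156 in the 3 drought libraries (4.10, SE 0.77, adjusted p = 0.00573). Glyur002055s00039240 (Scaffold02055, 27167 to 28546) rose from 1.19 ± 0.982 to 9.08, 22.9 and 127 (3.94, SE 0.79, adjusted p = 0.00993). The highest value of both was in drought library 3, which also carried underground transcripts, as described below.

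Salt changed 1628 aerial genes, 700 higher and 928 lower, and salt-drought changed 6848, 3049 higher and 3799 lower. After rescaling the salt-drought split was even, with 3584 higher and 3602 lower of 7186. Without control library 1 or 2, or salt library 1, the salt count fell to 738, 1056 and 1047, and without salt-drought library 3 the salt-drought count fell to 4534. With only the 2 groups fitted, 163 genes changed in salt, and Glyur000380s00017141 lost its call there. The same 2 genes rose most in both. Glyur000380s00017141 (Scaffold00380, 107256 to 109191) rose from 7.98 ± 4.70 to 122 ± 68.4 in salt (3.78, SE 0.59, adjusted p = 0.000655) and to 286 ± 126 in salt-drought (5.10, SE 0.59, adjusted p = 7.58e-06). Glyur000027s00001583 (Scaffold00027, 466170 to 468439) rose from 1.69 ± 0.456 to 34.9 ± 15.8 (3.64, SE 0.28, adjusted p = 3.15e-07) and 44.7 ± 7.62 (4.08, SE 0.28, adjusted p = 2.21e-08). In salt the largest falls were in 2 genes of Scaffold00098, Glyur000098s00007983 (103495 to 117710, overlapping another gene; 76.4 ± 5.90 to 5.40 ± 2.53, -3.68, SE 0.41, adjusted p = 2.28e-05) and Glyur000098s00007980 (84971 to 85933; 21.6 ± 2.79 to 0.852 ± 0.484, -3.63, SE 0.24, adjusted p = 1.35e-07). In salt-drought they were in the genes that fell most in drought, Glyur000529s00019343 (2.39 ± 2.52, -6.55, SE 0.42, adjusted p = 1.3e-08) and Glyur000080s00008691 (10.3 ± 6.17, -5.16, SE 0.56, adjusted p = 3.86e-06). Salt-drought lowered 107 of 723 underground-enriched genes in aerial parts and raised 6 (camera adjusted p = 2.15e-05 at the preset correlation, 0.742 at the estimated one). Of 807 aerial-enriched genes 196 rose and 126 fell (adjusted p = 0.0495 and 0.722). The underground markers were lower in aerial salt-drought too, at 0.00136, 0.121 and 0.00611% of their underground level against 0.203, 0.280 and 0.275% in aerial controls, so less carry-over of underground RNA was not separated from the fall of the underground-enriched genes.

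**Figure D2:**
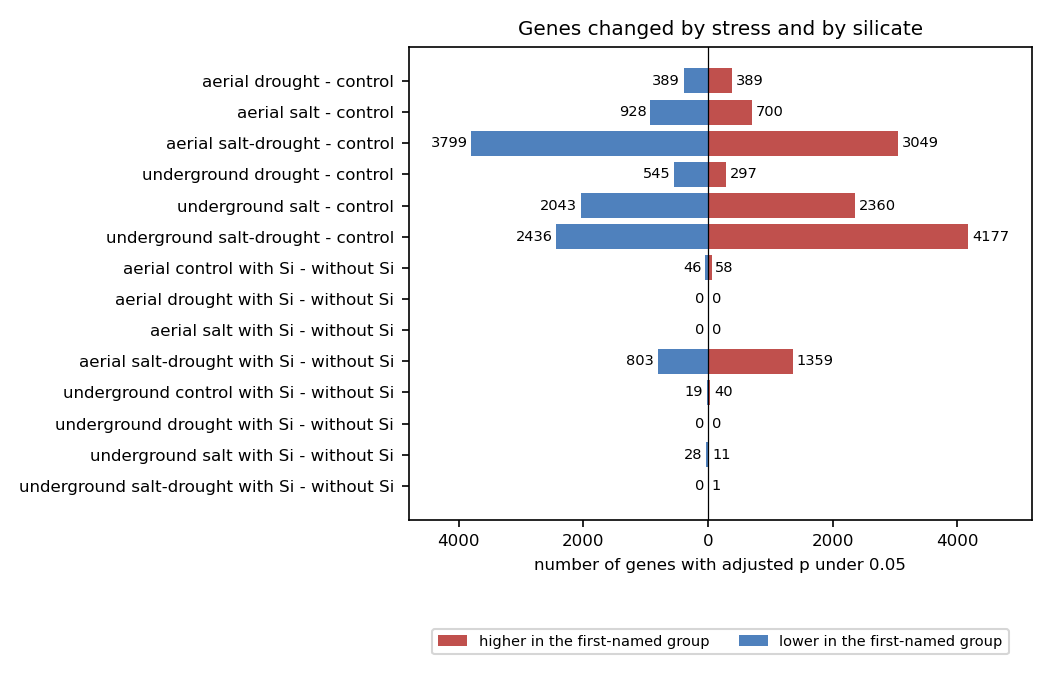
Numbers of genes past an adjusted p of 0.05 (limma) in each comparison within a plant part, 3 libraries per group. Right, higher in the first-named group; left, lower.

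2 aerial libraries carried transcripts that were otherwise almost absent above ground. The 28 underground markers stood at a median of 9.49% of their underground level (quartiles 7.27 to 14.8%) in drought library 3 and at 13.9% (11.1 to 16.3%) in library 2 of salt-drought with silicate. Libraries 3 and 1 of the latter group were at 1.72% and 0.914%, and every other aerial library at 0.662% or less. Of 23 aerial markers in underground libraries, the highest medians were 4.08% in salt-drought library 2 (22 markers) and 2.14% in library 3 of salt-drought with silicate. In drought, 30 of 723 underground-enriched genes rose in aerial parts and 3 fell (camera adjusted p = 1.13e-16 and 0.652). Underground-enriched genes were picked as low above ground, which favours rises. Of the 389 genes that rose, 131 were higher underground by at least 1 log2 unit in seedlings with silicate alone, and 258 were not. Among all tested aerial genes 3853 were and 19536 were not.

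**Figure D3:**
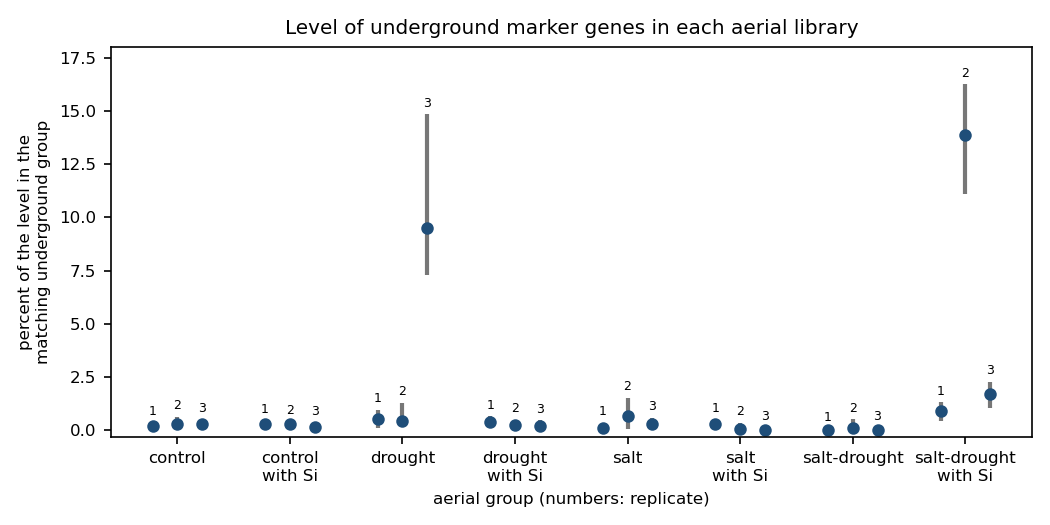
Level of 28 underground marker genes in each aerial library, as a percentage of the mean in the matching underground group. Points, medians; bars, quartiles; numbers, replicates.

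Underground, drought changed 842 of 24478 genes (297 higher, 545 lower), salt 4403 (2360 higher, 2043 lower) and salt-drought 6613 (4177 higher, 2436 lower). The median of all tested genes moved by 0.11 in underground salt-drought, and after rescaling 6388 genes changed, 3147 higher and 3241 lower, so the excess of rises goes with that shift. In salt the balance turned after rescaling, with 2144 higher and 2443 lower of 4587. The drought count was 512, 547 and 550 without control library 2, control library 3 or drought library 2, and the salt count was 2664 without control library 3. With only the 2 groups fitted, 560 genes changed in drought and 1612 in salt. Glyur000529s00019343, the gene with the largest fall in aerial drought, fell from 229 ± 67.0 to 5.83 ± 2.44 in underground drought (-5.09, SE 0.69, adjusted p = 0.000166) and to 1.81 ± 1.10 in salt-drought (-6.41, SE 0.69, adjusted p = 2.5e-06). Glyur000149s00009546 (Scaffold00149, 30843 to 31418) fell from 167 ± 6.32 to 5.75 ± 3.38 in drought (-4.80, SE 0.60, adjusted p = 8.81e-05) and 2.28 ± 1.68 in salt (-5.82, SE 0.60, adjusted p = 3.5e-06). Glyur000195s00012851 (Scaffold00195, 131634 to 132452) fell from 133 ± 14.7 to 0.498 ± 0.374 in salt-drought (-6.51, SE 0.62, adjusted p = 6.63e-07). Glyur000098s00007980, which fell in aerial salt, was at 201 ± 37.0 in underground controls and, in underground salt, at 5.39 and 2.78 in libraries 2 and 3 and listed at 0 in library 1.

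In underground salt, Glyur003454s00042037 (Scaffold03454, 7697 to 8631) rose from 0.689 ± 0.613 to 18.8 ± 12.8 (3.40, SE 0.61, adjusted p = 0.000863) and Glyur001118s00030860 (Scaffold01118, 40615 to 43567) from 0.873 ± 0.605 to 15.1 ± 7.64 (3.06, SE 0.43, adjusted p = 0.000102). In salt-drought, Glyur000080s00008697 (Scaffold00080, 251284 to 256139) rose from 4.87 ± 0.594 to 110.1 ± 75.6 (3.98, SE 0.69, adjusted p = 0.000355) and Glyur000131s00012974 (Scaffold00131, 61923 to 62297) from 4.41 ± 4.16 to 68.6 ± 14.3 (3.92, SE 0.60, adjusted p = 0.000112). The rule also named Glyur008866s00047708 and Glyur001613s00035720 in drought. They are listed at 0 in control libraries 1 and 2, at 5.73 and 4.18 in library 3, and at 31.4, 25.5 and 25.6 and at 14.9, 19.3 and 18.1 in the drought libraries, so no fold is given. Their calls were lost in 6 and 5 of 11 alternatives, among them those without control library 1 or 2 or without any 1 drought library. Underground-enriched genes fell more often than they rose in salt (143 and 78 of 799, camera adjusted p = 0.000649 and 0.683) and in salt-drought (249 and 109, adjusted p = 6.62e-08 and 0.506). Aerial-enriched genes rose more often in all 3 stresses, 17 against 1 of 702 in drought (adjusted p = 8.51e-10 and 0.683), 46 against 5 in salt (adjusted p = 0.000404 and 0.741) and 113 against 11 in salt-drought (adjusted p = 0.0021 and 0.769). The same directions held after rescaling. Aerial-enriched genes were picked as low underground, which leaves little room for falls, so rises were favoured there. Aerial markers were also raised in underground drought, at 1.34, 1.33 and 1.42% of their aerial level in the 3 libraries against 0.413, 0.0741 and 0.0483% in controls. They stood at 0.516, 0.114 and 1.57% in the 3 salt libraries and at 0.150, 4.08 and 0.216% in the 3 salt-drought libraries, so only 1 library of each stood far above the controls. Carry-over of aerial RNA was not tested as a source of these class changes.

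The parts shared many changes. Of 21769 genes tested in both, 43 rose and 122 fell with drought in both parts, against 5.12 and 9.0 if the parts were independent, and 1 moved in opposite directions (14.2 if independent). For salt the numbers were 246, 387 and 43 (70.5, 79.5 and 154), and for salt-drought 964, 1047 and 352 (523, 384 and 961). Aerial and underground comparisons share no library, but control libraries of the same number deviated together across the parts (r from 0.24 to 0.32), as did some drought libraries (0.09 to 0.35), which can raise these overlaps. In a test chosen after this was seen, the response without silicate in one part was set against the response with silicate in the other. The correlation across genes fell from 0.46 to 0.29 and 0.23 for drought, from 0.41 to 0.28 and 0.24 for salt, and from 0.41 to 0.39 and 0.26 for salt-drought. The noise-corrected SD of the drought response was also lower with silicate, at 0.127 against 0.343 in aerial and 0.174 against 0.291 in underground parts. Over genes not higher underground the aerial SDs were 0.148 and 0.286. The noise correction is inexact for drought, and the underground slope given below does not show a smaller response. For drought this test therefore cannot tell shared deviations of the libraries from a response that may be weaker with silicate. With aerial drought, 3 genes rose and 76 fell in both (0.352 and 3.78 if independent), and 1 moved in opposite directions. Glyur000529s00019343 fell in each of the 6 stress comparisons, and 2 further genes named in at least 3 comparisons, Glyur000051s00003460 and Glyur000515s00023228, lost most of their underground expression under stress, as the figure shows.

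**Figure D4:**
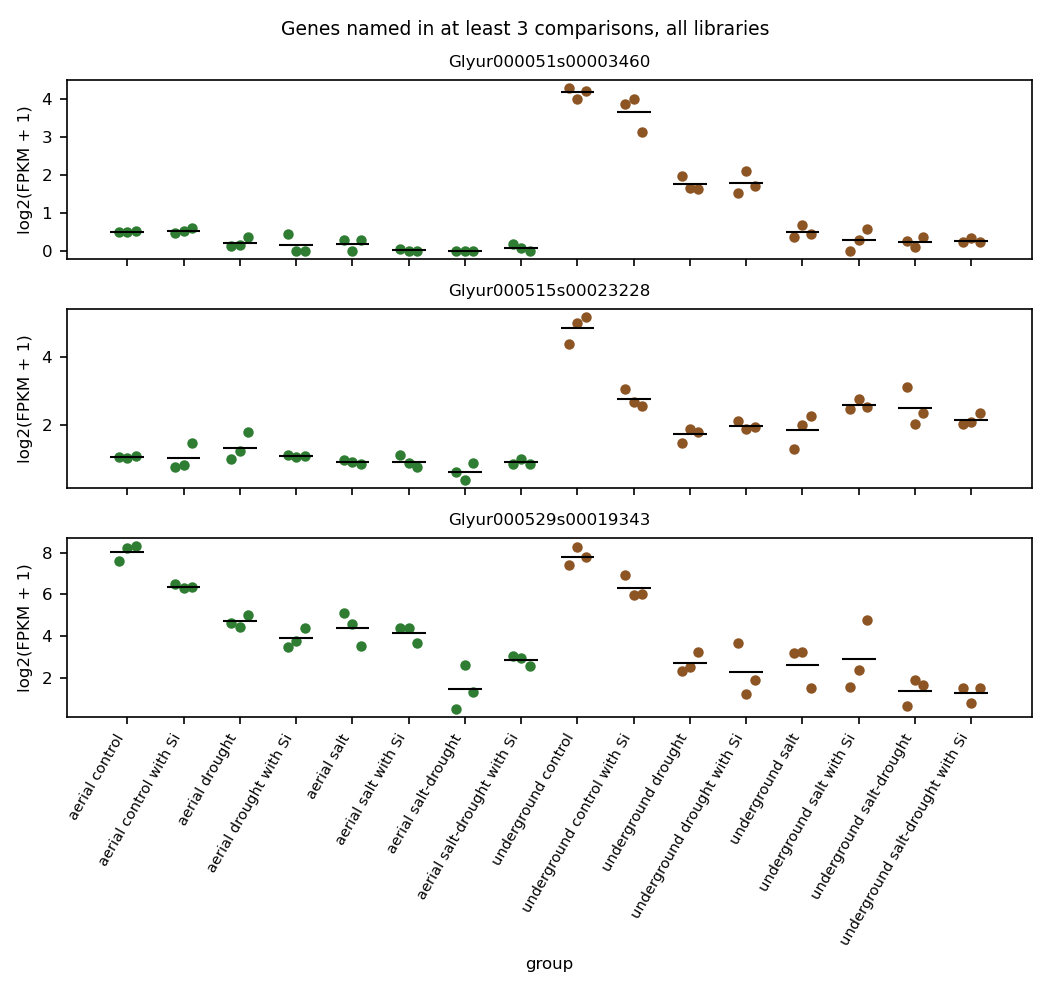
Genes named in at least 3 comparisons, log2(FPKM + 1) in all 48 libraries. Points, libraries; lines, means. Glyur000515s00023228 overlaps another annotated gene.

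Silicate alone changed 104 aerial genes in unstressed seedlings (58 higher, 46 lower). The count was 57 and 20 without control library 1 or 2, and 44 and 15 without library 1 or 2 of the silicate group. Glyur000732s00027540 (Scaffold00732, 83096 to 83890) rose from 48.9 ± 22.6 to 269 ± 107 (2.48, SE 0.35, adjusted p = 0.00329). With only the 2 groups fitted, 2 genes changed and this gene lost its call (adjusted p = 0.230). The other 3 genes the rule named lost theirs in 10, 8 and 6 alternatives. In drought and in salt silicate changed 0 aerial genes with limma, with 2254 and 1272 genes at an unadjusted p under 0.05. These were 9.64 and 5.44% of the genes tested, so the number in salt was close to that expected without any effect. Without drought library 1, 11 genes changed with silicate in drought.

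In aerial salt-drought, silicate changed 2162 genes, 1359 higher and 803 lower. After rescaling it changed 2589, 1387 higher and 1202 lower. With only the 2 groups fitted it changed 14 genes. In fits chosen after seeing the data, it changed 548 (309 higher, 239 lower) without the 2 aerial libraries that held the most underground RNA and 1375 (649 higher, 726 lower) over genes not higher underground, where the balance turned. The count was 346 without salt-drought library 3, and 481 and 1338 without library 2 or 3 of the silicate group. The largest rises were of the 2 genes of Scaffold01944 named above, Glyur001944s00035555 (0.898 ± 0.406 to 211, 4236 and 581; 8.75, SE 1.54, adjusted p = 0.00428) and Glyur001944s00035546 (1.68 ± 1.53 to 449.8, 3657 and 567; 8.70, SE 1.55, adjusted p = 0.00435). Both meet the rule for underground markers, at 33050 ± 6253 and 34836 ± 3021 in underground salt-drought with silicate. Of 723 underground-enriched genes 298 rose and 0 fell (limma), with a median log2 change of 1.33 (camera adjusted p = 5.95e-44 and 0.506), while of the aerial-enriched genes 11 rose and 54 fell (adjusted p = 9.58e-07 and 0.506). Underground-enriched genes were picked as low above ground, which leaves little room for falls. The underground markers rose too, at 0.914, 13.9 and 1.72% of their underground level in silicate libraries 1, 2 and 3. In salt-drought libraries 1, 2 and 3 they were at 0.00136, 0.121 and 0.00611%, so carry-over of underground RNA was not separated from these rises. Of the 803 falls, 4 were of genes higher underground and 799 were not, and of the 1359 rises 651 and 708. Among all tested aerial genes 3853 were higher underground and 19536 were not. Genes higher underground are lower above ground, which limits falls among them. Glyur000130s00006890 (Scaffold00130, 57817 to 58038) fell from 17.4 ± 1.80 to 3.73 ± 2.10 (-2.06, SE 0.37, adjusted p = 0.00435). With only the 2 groups fitted, this gene and Glyur001944s00035555 lost their calls. Of 1267 genes changed both by salt-drought and by silicate within it, 1231 moved in opposite directions, 999 of 1030 among genes not higher underground. The salt-drought libraries enter both comparisons, which favours opposite directions.

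Underground, silicate changed 59 genes in unstressed seedlings (40 higher, 19 lower), 0 in drought (limma), 39 in salt (11 higher, 28 lower) and 1 in salt-drought. In drought 1177 genes were at an unadjusted p under 0.05 (limma), 4.81% of those tested and no more than expected without any effect. The unstressed count was 4 and 20 without control library 2 or 3 and 28, 25 and 8 without library 1, 2 or 3 of the silicate group. The drought count was 2 without library 2 of the silicate group. The salt count ranged widely, with 0, 785 and 66 genes without salt library 1, 2 or 3 and 2, 0 and 5 without library 1, 2 or 3 of the silicate group. With only the 2 groups fitted, 10 genes changed in unstressed seedlings, 1 in drought, and 0 in salt and in salt-drought (limma; 2478 and 1914 at an unadjusted p under 0.05). The salt-drought count was 2 without salt-drought library 1 and 510 without library 3 of the silicate group. In unstressed seedlings Glyur001184s00030528 (Scaffold01184, 47219 to 48034) rose from 2.66 ± 0.804 to 15.1 ± 3.68 (2.13, SE 0.33, adjusted p = 0.00915), and Glyur000515s00023228 (Scaffold00515, 110951 to 112300) fell from 28.5 ± 7.97 to 5.83 ± 1.34 (-2.09, SE 0.27, adjusted p = 0.00164). Glyur000019s00002144 (Scaffold00019, 353074 to 362647) fell from 17.0 ± 3.56 to 5.52 ± 0.777 (-1.45, SE 0.17, adjusted p = 0.00164). In salt, Glyur001118s00030860, which salt had raised to 15.1 ± 7.64, was at 2.39 ± 1.11 with silicate (-2.20, SE 0.43, adjusted p = 0.0466), a call lost in 7 of 11 alternatives. The 1 gene in salt-drought was Glyur000232s00013783 (Scaffold00232, 240936 to 241625), at 1.86 ± 0.381 without and 17.2 ± 3.47 with silicate (2.66, SE 0.25, adjusted p = 7.13e-05). It lost its call with only the 2 groups fitted, as did the 3 genes named for unstressed seedlings, and Glyur001184s00030528 also without control library 2 (4 genes changed) or library 3 of the silicate group (8 genes changed).

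The effect of silicate in aerial parts differed between salt-drought and unstressed seedlings for 484 genes (280 higher, 204 lower). The count was 305 with the replicate number as a block, 744 (373 higher, 371 lower) after rescaling, 305 without a filter, and 27 without the 2 aerial libraries that held the most underground RNA. It was 189 and 124 without control library 1 or 2, 235, 33 and 217 without library 1, 2 or 3 of control with silicate, 25 without salt-drought library 3, and 1045, 29 and 261 without library 1, 2 or 3 of salt-drought with silicate. Glyur000178s00013194 (Scaffold00178, 91332 to 92861) rose with silicate from 60.5 ± 5.97 to 106 ± 6.67 without stress and fell from 241 ± 49.4 to 153 ± 10.6 in salt-drought (interaction -1.44, SE 0.19, adjusted p = 0.00579). For drought and salt the interactions held 0 genes with limma, with 1573 and 1782 at an unadjusted p under 0.05. The drought interaction held 1, 1 and 3 genes without control library 3, library 3 of control with silicate or drought library 3. The salt interaction held 5, 16 and 3 without control library 3, library 3 of control with silicate or salt library 2.

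Underground, the silicate effect differed for 130 genes with salt (52 higher, 78 lower; 79 and 82 of 161 after rescaling), 0 with drought (limma; 1646 at an unadjusted p under 0.05) and 1 with salt-drought. The salt interaction was 50, 30 and 38 without control library 1, 2 or 3, 71 and 35 without library 1 or 2 of control with silicate, 45, 270 and 42 without salt library 1, 2 or 3, and 30, 15 and 84 without library 1, 2 or 3 of salt with silicate. The drought interaction was 2 without control library 1, and 1 and 2 without library 1 or 2 of drought with silicate. The salt-drought interaction was 7, 0 and 0 without control library 1, 2 or 3, 0, 2 and 0 without library 1, 2 or 3 of control with silicate, 0 and 3 without salt-drought library 1 or 2, and 0 and 339 without library 2 or 3 of salt-drought with silicate. Glyur000324s00015435 (Scaffold00324, 75767 to 77201) rose with silicate from 3.34 ± 0.198 to 13.3 ± 2.26 without stress and fell from 21.7 ± 8.34 to 6.73 ± 0.860 in salt (-3.21, SE 0.43, adjusted p = 0.00418). The 1 gene with salt-drought was Glyur000445s00019997 (Scaffold00445, 16402 to 19161, overlapping another gene; -1.58, SE 0.22, adjusted p = 0.0212), a call lost in 7 of 16 alternatives.

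Salt-drought departed from the sum of salt and drought on the log2 scale for 1021 aerial genes (420 higher, 601 lower than the sum) and 437 underground genes (256 higher, 181 lower). After rescaling, 1086 aerial genes departed, 589 higher and 497 lower, so the aerial direction depends on the scaling. The aerial count was 470 and 454 without control library 2 or 3, 509 and 624 without drought library 1 or 2, 2130 and 407 without salt library 1 or 3, and 579 and 358 without salt-drought library 2 or 3. The underground count was 224, 289 and 261 without control library 2, drought library 1 or salt-drought library 1. In aerial parts Glyur001184s00030528 rose from 18.3 ± 2.46 to 119.9 ± 36.8 with drought and 126 ± 44.3 with salt, but only to 78.4 ± 9.96 with both (-3.23, SE 0.38, adjusted p = 0.000599). Underground, Glyur000232s00013783 rose from 9.18 ± 3.57 to 33.6 ± 7.19 with drought and 27.3 ± 5.73 with salt, and fell to 1.86 ± 0.381 with both (-5.09, SE 0.36, adjusted p = 4.54e-07).

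The response to stress differed between the parts for 119 genes with drought (52 higher, 67 lower underground), 1060 with salt (626 and 434) and 4661 with salt-drought (3384 and 1277). The drought count was 63 (20 and 43) with a replicate block shared by the parts and 201 (80 and 121) without the 2 aerial libraries that held the most underground RNA, 2 fits chosen after seeing the data. After rescaling the drought split was 64 and 66 of 130, the salt split 589 and 593 of 1182 and the salt-drought split 2560 and 2141 of 4701. Before rescaling the median of all tested genes stood at -0.028 for drought, 0.059 for salt and 0.14 for salt-drought. The drought count was 78 without aerial control library 2, 54, 70 and 195 without aerial drought library 1, 2 or 3, 73 and 61 without underground control library 2 or 3, and 60 and 79 without underground drought library 1 or 2. The salt count was 655, 579 and 525 without aerial control library 2, aerial salt library 1 or underground control library 3, and the salt-drought count was 3070 without aerial salt-drought library 3. Glyur000742s00025064 (Scaffold00742, 34788 to 36884, overlapping another gene) rose from 17.6 ± 2.34 to 289.7 ± 73.3 in aerial salt-drought and fell from 573 ± 52.3 to 356 ± 33.5 underground (-4.62, SE 0.44, adjusted p = 3.47e-08). Glyur001208s00036579 (Scaffold01208, 49299 to 50645) rose from 60.9 ± 11.1 to 81.5 ± 4.30 in aerial salt and fell from 97.9 ± 14.7 to 24.9 ± 0.355 underground (-2.35, SE 0.24, adjusted p = 1.14e-07). Glyur000051s00003460 (Scaffold00051, 422812 to 423267) fell underground from 17.0 ± 1.74 to 0.422 ± 0.174 in salt and was at 0.418 ± 0.0200 in aerial controls and 0.143 ± 0.124 in aerial salt, where library 2 is listed at 0.

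Across all tested genes, the response to stress in seedlings given silicate was set against the response without silicate, 2 comparisons that share no library. The noise-corrected slope was 0.384 (jackknife SE 0.114) for aerial drought, 0.816 (0.287) for aerial salt and 0.485 (0.124) for aerial salt-drought. Underground it was 0.807 (0.099), 0.926 (0.199) and 0.781 (0.157). A slope under 1 arises when silicate moves stressed libraries back, or controls toward the stress level. The slope of the silicate change within stress on the stress response was -0.349 (SE 0.171), 0.182 (0.231) and -0.339 (0.128) for aerial drought, salt and salt-drought, and 0.231 (0.114), 0.069 (0.201) and -0.120 (0.154) underground. The slope of the silicate change in controls was 0.268 (0.114), 0.367 (0.121) and 0.176 (0.066) in aerial parts and 0.424 (0.096), 0.144 (0.050) and 0.0996 (0.0341) underground. Only the aerial drought and aerial salt-drought slopes lie more than 2 SE under 1, so a smaller response is not shown for the other slopes. The noise-corrected correlation came to 1.35 in underground drought and 1.03 in aerial drought. Both exceed the limit of 1, so the noise correction is inexact there. In aerial salt-drought the correlation was 0.606, so the low slope there also holds a different pattern across genes. Over genes not higher underground the aerial slopes of the stress response were 0.459 (0.165), 0.753 (0.240) and 0.595 (0.103). Over those genes the silicate change within stress had slopes of -0.104, 0.127 and -0.235, with no SE computed. The same computation gave -0.351, 0.184 and -0.339 over all genes, so the slope in aerial drought came mostly from genes higher underground.

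**Figure D5:**
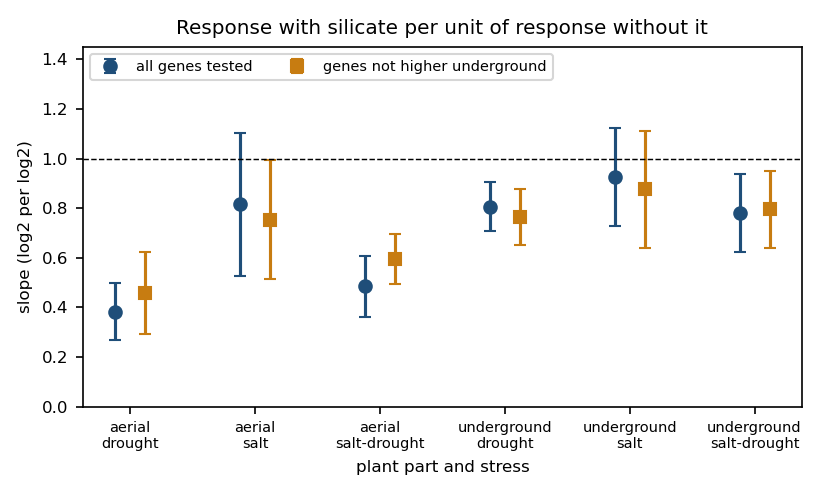
Slope across genes of the stress response with silicate on the response without it, with jackknife standard errors over 12 libraries. Dashed line, equal responses.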

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

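The tests of chance splits were planned; the reading of which relabellings reverse 1 pair was chosen after the results were seen. The difference in stress response between plant parts, tested as an interaction, was singled out for a closer look because the parts' effects differed: 119 genes with drought, 1060 with salt and 4661 with salt-drought. Of 100 relabellings of stressed and control libraries within each part, 2 gave as many genes for salt-drought, the real one included (highest other 4810). For drought 13 did (highest other 2227) and for salt 11 (highest other 2649). Mixing stressed and control libraries also removes the stress response of each part and adds it to the spread. The relabellings therefore do not exclude chance for a difference between the parts under any stress. Relabellings that reverse most labels of 1 pair turn the difference between the parts into a sum, and 11 of the 12 others as large for drought, 8 of 10 for salt and 1 of 1 for salt-drought were of that kind. The highest among the rest were 124, 1318 and 2872. For drought and salt these also exceeded the real 119 and 1060, and they are not of that kind. Whether the counts of the reversed kind come from a stress response shared by the parts was not tested. With a replicate block shared by the parts, chosen after seeing the data because control libraries of the same number deviate together, the drought count was 63. It was 78 without aerial control library 2, 54, 70 and 195 without aerial drought library 1, 2 or 3, 73 and 61 without underground control library 2 or 3, and 60 and 79 without underground drought library 1 or 2. The salt count was 655, 579 and 525 without aerial control library 2, aerial salt library 1 or underground control library 3. The salt-drought count was 3070 without aerial salt-drought library 3. Aerial drought library 3 held underground transcripts, but why the count was higher without it was not tested.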

How the results depend on the processing

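The fits without 2 aerial libraries, over genes not higher underground, and with a block shared between the parts were chosen after seeing the data, as was leaving libraries out of the slopes. Counts stayed within 1.5 times the reported one in 25 of 26 results with a pseudocount of 0.1, 19 of 26 without a filter, 23 of 26 after rescaling and 24 of 26 with the replicate number as a block, but in 3 of 14 when only the 2 groups compared were fitted. With the pseudocount the aerial silicate by salt interaction had 1 gene. Without a filter, aerial silicate in drought had 12 genes, aerial silicate by salt-drought 305, aerial salt by drought 626, underground silicate in salt 23, and the underground silicate interactions 1 (drought), 54 (salt) and 2 (salt-drought). After rescaling, aerial silicate in drought had 1, aerial silicate by salt-drought 744 and underground silicate by salt-drought 0 (limma; 2231 at an unadjusted p under 0.05). With the block, aerial silicate by salt-drought had 305 and underground silicate in salt 25. With 2 groups fitted, aerial drought had 54, salt 163, silicate in control 2, in drought 1 and in salt-drought 14; underground drought had 560, salt 1612, silicate in control 10, in drought 1, in salt 0 and in salt-drought 0 (limma; 2478 and 1914 at an unadjusted p under 0.05). Without the 2 aerial libraries that held underground RNA, aerial silicate in salt-drought had 548, its interaction 27 and the part by drought interaction 201. Over genes not higher underground, aerial silicate in salt-drought had 1375 and aerial silicate by salt 3. With a block shared between the parts, the part by drought interaction had 63. Over genes that differed between any groups, the underground drought slope was 0.649 against 0.807. With each library left out in turn the counts ranged as follows. Aerial: drought 317 to 655, salt 738 to 1613, salt-drought 4534 to 6093; silicate in control 15 to 146, drought 0 to 11, salt 0 to 0, salt-drought 346 to 2146; silicate by drought 0 to 3, by salt 0 to 16, by salt-drought 25 to 1045; salt by drought 358 to 2130. Underground: drought 512 to 702, salt 2664 to 4155, salt-drought 4655 to 6267; silicate in control 4 to 43, drought 0 to 2, salt 0 to 785, salt-drought 1 to 510; silicate by drought 0 to 2, by salt 15 to 270, by salt-drought 0 to 339; salt by drought 224 to 435. Between parts: control 14419 to 14788, drought 54 to 195, salt 525 to 1231, salt-drought 3070 to 4694. Slopes ranged from 0.285 to 0.469, 0.656 to 1.02 and 0.409 to 0.570 in aerial drought, salt and salt-drought, and from 0.745 to 0.903, 0.670 to 1.06 and 0.674 to 0.862 underground. Of 858 alternative values of 64 named gene results, 761 kept their call, 97 lost it and 0 reversed. The gene list tests were not run, since no identifier carries a name.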

Other observations

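The patterns and gene classes below were noticed in these data and then tested on them. Of the tests, the splits, the share of underground RNA and the libraries left out were set before their results were seen; the tests of noise, underground RNA and moving controls for the smaller salt-drought response were chosen after.

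Many genes that changed with silicate alone also changed with drought in the other plant part, in the same direction, but whether silicate moves genes toward the stress level stays open. Of 100 aerial genes changed by silicate in unstressed seedlings and tested underground, 40 also changed in underground drought, against 3.73 if independent, all 40 in the same direction. Of 55 underground silicate genes, 15 changed in aerial drought (1.92 if independent), 15 in the same direction. Across all genes the 2 changes correlated with r = 0.287 and 0.274, and the highest of the other 9 splits of the libraries gave 0.165 and 0.171. For salt the correlations were 0.165 and 0.173 (other splits 0.211 and 0.140), and for salt-drought 0.117 and 0.0945 (0.205 and 0.0987). These comparisons share no library, but control libraries of the same number deviated together across the parts (r from 0.24 to 0.32), which by itself gives such a correlation, so a shared origin of the controls is not excluded. In a test chosen after this was seen, against the stress response of silicate-treated groups in the other part, which avoids those controls, r was 0.102, -0.016 and -0.003 for aerial silicate and -0.006, -0.129 and -0.066 for underground silicate (drought, salt, salt-drought). Of the aerial silicate genes, 1 rose and 16 fell in underground drought as well (0.0505 and 0.453 if independent), and 0 moved in opposite directions. For underground salt 6 rose and 17 fell in both (5.16 and 3.87) and 15 moved in opposite directions (8.96), and for salt-drought 8, 22 and 16 (2.98, 4.09 and 7.44). Of the underground silicate genes, 0 rose and 2 fell in aerial drought as well (0.00873 and 0.0211), with 0 opposite. For aerial salt 1 rose and 3 fell in both and 7 were opposite (0.808, 0.405 and 1.27), and for salt-drought 4, 5 and 11 (2.32, 1.07 and 3.42). Moves in the same direction and opposite moves were thus both in excess in all 4 salt and salt-drought comparisons. If silicate moved the controls of both parts this second test would lower r as well, so neither reading is excluded. With Si the mean of Glyur000529s00019343 was 82.0 ± 5.52 against 269.5 ± 68.4 in aerial and 82.1 ± 33.2 against 229 ± 67.0 in underground controls. Neither difference was called (limma, adjusted p = 0.1 and 0.522). The gene was named for its fall from these same untreated controls, which favours high values there.

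Genes changed the same way also lay side by side more often than in most permutations. Neighbouring pairs numbered 59 in aerial salt (30.8 on average over 1000 permutations of positions, highest 50), 660 in aerial salt-drought (528, 594), 294 in underground salt (212, 255) and 683 in underground salt-drought (507, 575). In aerial drought there were 14 (6.77, 17), in underground drought 19 (8.59, 19) and in aerial salt-drought with silicate 70 (55.9, 78), which the permutations reached. Neighbours were consecutive tested genes of a scaffold, and pairs with a gene that overlaps another annotated gene were left out. The permutations drew calls from all tested annotated genes, overlapping ones included, so they are not an exact measure of chance for these pairs. Likeness of neighbours in expression level was not allowed for. Shared reads of duplicated genes would give the same picture.

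Silicate in aerial salt-drought went with higher values of underground-enriched genes (camera adjusted p = 5.95e-44 at the preset correlation, 0.506 at the estimated one, so the class change is not established). A mixture with underground RNA at the marker share of each library predicts 0.48 of the median 1.26 rise in log2 units for 639 risen genes higher underground, a median ratio of 0.404 (quartiles 0.276 to 0.597), so underground RNA may explain part of these rises, and a response of the seedlings to silicate stays open beside it. For rises of genes not higher underground the ratio was 0.0738, and for falls 0.0617. Shares this small can move genes of these kinds only little, so low ratios were bound to follow. They show only that a mixture at the marker share is too small for the typical size of these changes. Without library 2 of the silicate group 481 of 2162 genes were left, but without salt-drought library 3, which held almost no underground RNA (0.00611%), the count was 346, and without library 3 of the silicate group 1338. Only these 3 of the 6 libraries moved the count beyond 1.5 times, and it was 2146 without library 1 of the silicate group. An effect of the mixed library therefore cannot be told apart from how far the count hangs on certain single libraries.

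Aerial drought library 3 held underground transcripts as well. Without it 655 of 778 genes changed, against 514, 317 and 454 without control library 1, 2 or 3 and 402 and 445 without drought library 1 or 2, so it does not carry the aerial drought count. The mixture predicts a median of 0.164 of the rise of genes higher underground. Only called genes were scored, and RNA mixed into 1 library adds spread, which works against a call. A low ratio was thus favoured by the choice of genes. It shows only that a mixture at the marker share is too small for the typical size of these called rises. For the other genes it predicts 0.0297 of the change, a low value that was bound to follow from so small a share. A response of the seedlings to drought stays open as the biological explanation.

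The aerial response to salt-drought was smaller with silicate. Its slope of 0.485 (SE 0.124) is corrected for noise, it was 0.595 (SE 0.103) over genes not higher underground, the silicate change within salt-drought had a slope of -0.339 (SE 0.128) on the stress response, which moving controls alone would leave at 0, and the highest slope with 1 library left out was 0.570. Controls moved as well, with a slope of 0.176 (SE 0.066), and so made up part of the shortfall. These values argue against noise, underground RNA, the controls and a single library as the whole cause of the low slope. A hypothesis is that silicate may dampen the aerial response to salt-drought. A change in the pattern of that response across genes stays open beside it. Aerial drought had a lower slope, 0.384 (SE 0.114), with a silicate change within stress of -0.349 (SE 0.171), and was not weighed. Over genes not higher underground the slope of the silicate change within stress was -0.104 for drought and -0.235 for salt-drought, with no SE computed.

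For pairs of groups only 10 splits of the 6 libraries exist, too few to reach a share under 0.05. The real split gave the highest count in 1 of 10 for aerial drought (778; highest other 0), salt (1628; 1), salt-drought (6848; 0), silicate in control (104; 0) and in salt-drought (2162; 0), for underground drought (842; 1), salt (4403; 3), salt-drought (6613; 0) and silicate in control (59; 1), and for the parts (15457; 6). For underground silicate in salt 2 of 10 were as large (39; highest other 361) and in salt-drought 5 of 10 (1; 94), which points to a structure of these libraries other than silicate. For silicate in aerial drought (0; 2), aerial salt (0; 5) and underground drought (0; 1) all 10 were, with limma counts of 2254, 1272 and 1177 at an unadjusted p under 0.05.

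For interactions, of 100 relabellings, few gave as many genes for aerial silicate by salt-drought (1 as large, 484; highest other 403), aerial salt by drought (1; 1021; 661), underground silicate by salt (2; 130; 177) and underground salt by drought (3; 437; 865). Relabelling within pairs of groups also removes effects that the pairs hold in common and adds them to the spread. A low share therefore does not exclude chance for the interaction itself. More did for underground silicate by salt-drought (24; 1; 11), and all did for aerial silicate by drought (100; 0; 92), by salt (100; 0; 36) and underground silicate by drought (100; 0; 6). For these last interactions limma gave 1573, 1782 and 1646 genes at an unadjusted p under 0.05.

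Exact zeros deserve care in this table. Glyur001446s00035042 is listed at 0 in 21 libraries and lies between 45.2 and 260.3 FPKM in the other 27.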
